A study of Mus musculus with 2 samples.

How the data were processed

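Small RNA under 30 nucleotides by the size label was sequenced from 2 pools of mouse stomach at embryonic day 16.5. The authors deposited, per library, a table of raw read counts for 1973 genes and 4 summary totals. Per the file headers, reads were aligned to mm10 and counted per gene of the GENCODE M4 annotation. The aligner, the counter, the adapter trimming and their versions are not given in the sources used here. Each deposited table gives the counts without regard to strand, on the sense strand and on the opposite strand, and the last pair added up to the first in every gene. Counts belong to whole hairpin genes, so the mature arms of a hairpin were not told apart.

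The summary totals named no gene and were left out of library sizes and tests. Reads placed in several positions made up 25.1% of the reads of replicate 1 and 25.2% of replicate 2, unmapped reads 21.3% and 20.3%, and reads outside any counted gene 2.81% and 3.11%, with 0 ambiguous reads. Since reads placed in several positions form a total of their own, it is inferred that no gene count holds them. A gene with identical copies can then hold few counted reads, and a value near 0 there does not show absence. Reads on the opposite strand were 3.35% and 2.82% of the reads assigned to genes. Sense-assigned reads came to 49.1% of all reads in replicate 1 and 50.0% in replicate 2, and the floor of 3 counts equals 0.388 and 0.376 CPM.

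Symbols, coordinates, host genes and hairpin GC content were taken from the GENCODE M21 annotation and sequence of GRCm38, the assembly that mm10 names. Of the 1973 gene identifiers, 1894 matched. The 79 without a match held 3 sense reads in both libraries together. A place in an exon or intron refers to a gene annotated on the same strand.

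Levels were computed as counts-per-million (CPM) of the sense-assigned reads, and means and SDs are over the 2 libraries. For ratios the libraries were scaled by trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, with 0.5 added to each count. Genes at a mean of 10 CPM or more were tested with a two-sided exact binomial test of both counts against the effective library sizes, with Benjamini-Hochberg adjustment, a threshold of 0.05 and at least 2-fold. The test compares 2 libraries and carries no spread among animals. The biological coefficient of variation came from edgeR with an intercept only. DESeq2 1.42.0 gave alternative size factors. Shares in single libraries have exact Clopper-Pearson 95% intervals. Correlations used a pseudocount of 1 CPM. Lists were ranked by the median log2 level of their members among 10000 random lists of the same size, which describes these libraries and is not a test over replicates. Among genes with a Mir symbol and a read, those with numbered copies were compared with the others by 100000 permutations of the copy label. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

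The groups, the main tests, most alternatives, the 28 gene lists and the rule for named genes were fixed before the data were examined. A further 2 alternatives and most tests of explanations were added later, as stated where they are given. The rule took the 25 genes with the highest mean CPM, up to 3 members of each list with the highest mean CPM, and up to 5 genes in each direction with the largest fold between libraries among those past the test with at least 100 reads. Genes named outside the rule were chosen after their values were seen, among them Mir30b, the genes called with total-read scaling alone, the multi-copy genes with few or no reads, the 6 Dlk1-Dio3 genes that differed, the low members of genomic clusters, and the genes with reads on the opposite strand. The alternatives were other expression thresholds, the count that ignores strand, TMM, DESeq2 and total-read scaling, other pseudocounts, no filter on low counts, no minimum fold, other list summaries and backgrounds, other definitions of a copy, and each library left out. Where 1 library was left, its value has no spread.

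The between-library test was run on simulated data with the depths of these libraries over 289 genes. It called 100% of 150 genes planted at 3-fold, 0% of 50 planted at 1.5-fold, which lies under the fold threshold, and 0% of 89 unchanged genes. These simulated counts carried counting error only, while the real libraries had an estimated coefficient of variation of 0.294. The 0% is therefore not the rate of calls among unchanged genes in the real libraries. Simulated coefficients of variation of 0.1, 0.3 and 0.5 were estimated at 0.0989, 0.314 and 0.489.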

Results

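Small RNA libraries of mouse stomach at embryonic day 16.5 were profiled to describe which microRNA (miRNA) genes the tissue expressed late in gestation. The series held 1 group of 2 biological replicates, each a pool of stomachs from male and female embryos of the B6NCrl strain. Replicate 2 was made from 41 embryos, and the number pooled for replicate 1 is not given in the labels. Replicate 1 held 15746238 reads, of which 7734578 were assigned to miRNA genes in the sense direction. Replicate 2 held 15958656 reads, of which 7983714 were assigned in that direction. No second tissue, age or treatment was present, so no contrast between conditions was made. The comparisons below are between miRNA genes within the tissue and between the 2 libraries. Both libraries carry one donor label, and p-values between them describe these libraries and not a difference between conditions. Intervals and floors cover counting error only, since the reads carry no molecular identifiers in the sources used here.

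The first question was which miRNA genes made up the profile. Mir143, a miRNA gene of smooth muscle, took 19.6% ± 0.135 (SD, n = 2) of the sense-assigned reads, or 195813 ± 1350 in counts-per-million (CPM). It lies on chromosome 18 from 61649196 to 61649258 on the minus strand (GRCm38, the same assembly as mm10), outside any gene annotated on its own strand. Mir99a followed at 63941 ± 1248 CPM (SD, n = 2), in an intron of its host transcript Mir99ahg on chromosome 16 from 77598936 to 77599000. Mirlet7g, in an intron of Wdr82, stood at 52768 ± 11516 CPM, and Mirlet7i, in an exon of D630033A02Rik, at 48456 ± 2196 CPM. Mir335, in an intron of the imprinted gene Mest, was the fifth most abundant gene at 36512 ± 7721 CPM. Mir143 was higher than Mir99a in both libraries, and the gap in counted reads was many times the SD of either gene. An SD over 2 libraries does not cover a bias between miRNA sequences that both libraries would share. Mirlet7g and Mirlet7i differed by less than the SD of Mirlet7g, so their order is not settled.

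The genes ranked next included Mir10a, which lies on chromosome 11 from 96317165 to 96317274 and belongs to the miRNAs of the Hox clusters, at 29647 ± 2450 CPM (SD, n = 2). Mir126a, the endothelial miRNA gene in an exon of Egfl7, stood at 29039 ± 14.7 CPM. Mir26b in an intron of Ctdsp1 stood at 28065 ± 3621 CPM, and the epithelial gene Mir429 at 23612 ± 3020 CPM. Mir203, a miRNA gene of stratified epithelium, reached 22271 ± 7172 CPM, with 133033 reads in replicate 1 and 218299 in replicate 2. The other genes among the 25 highest were Mir130a, Mir23b, Mir322, Mir23a, Mir17, Mir21a, Mir30e, Mir200c, Mirlet7d, Mir99b, Mir411, Mir205, Mir375, Mir200b and Mir127, from 21971 CPM for Mir130a down to 8433 CPM for Mir127. Mir23a, Mir23b and Mir411 share a stretch of 20 bases with the hairpin of another miRNA gene, and their levels are uncertain where reads matched both.

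**Figure D1:**
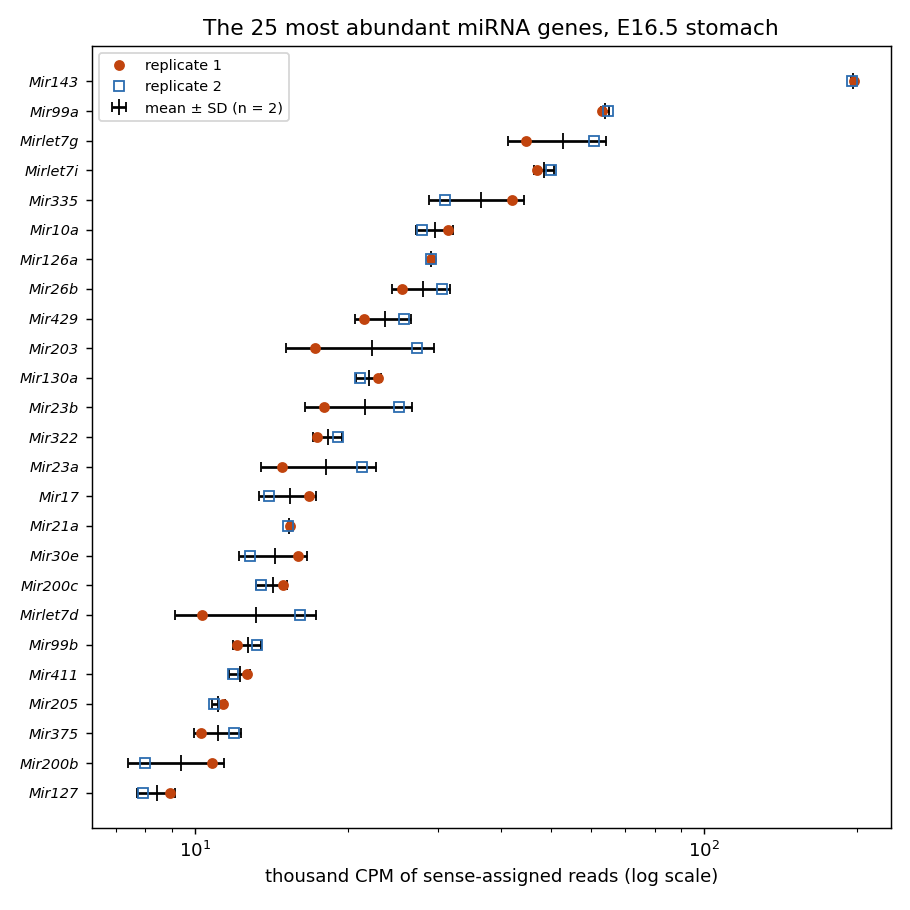
Levels of the 25 miRNA genes with the highest mean, in CPM of sense-assigned reads on a log axis whose ticks are in units of 1000 CPM. Circles and squares are replicates 1 and 2, and the bar gives the mean and SD of both; Mir143 stands apart at a mean of 195813 CPM, above Mir99a at 63941 CPM.

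The reads were concentrated in few genes. The 10 most abundant genes held 53.0% ± 1.73 (SD, n = 2) of the sense-assigned reads. In replicate 1 the share was 51.8% (exact Clopper-Pearson 95% interval 51.76% to 51.83%), and in replicate 2 it was 54.2% (54.20% to 54.27%). The 25 most abundant genes held 74.8% ± 2.40, and the 100 most abundant 96.3% ± 0.453. A level of at least 10 CPM in both libraries was reached by 277 of the 1973 genes in the count tables, with 289 genes at that level in replicate 1 and 281 in replicate 2. A sense read in at least 1 library was seen for 751 genes. The other 1222 genes had no sense read. For reads placed in 1 position, this allows up to 0.388 CPM in replicate 1 and 0.376 CPM in replicate 2. No such bound holds for reads placed in several positions. Among genes with a Mir symbol and no read, 104 share a 20-base stretch with another hairpin. Without Mir143 the share of the 10 most abundant of the other genes was 44.3%.

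Lists of miRNA genes fixed before the data were examined were then compared by their share of the sense-assigned reads. The smooth muscle list of miR-143 and miR-145 was the largest in counted reads at 19.97% ± 0.331 (SD, n = 2), and Mir143 made up nearly all of it. Mir145a, which lies beside Mir143 on chromosome 18 from 61647825 to 61647894, stood at 3928 ± 1963 CPM, with 41123 reads in replicate 1 and 20279 in replicate 2. The let-7 family, typical of differentiated cells, held 13.0% ± 1.82, and all 10 of its measured members reached 10 CPM in both libraries. Mirlet7e and Mirlet7f-1 had no row of their own and are not in this share. Mirlet7c-1 shares a 20-base stretch with another hairpin, so reads that matched several hairpins may be missing. The let-7 share is therefore uncertain, and its order against the smooth muscle list holds for counted reads only. The family of miR-125, miR-99 and miR-100 held 8.82% ± 0.0206, led in counted reads by Mir99a, Mir99b and Mir100. Its numbered copies Mir125b-1 and Mir125b-2 stood at 513 and 671 CPM. Reads that matched both may be missing, so this share and the order of members are uncertain. The imprinted Dlk1-Dio3 cluster on chromosome 12 held 6.54% ± 0.742, with 40 of its 44 measured members at 10 CPM or more in both libraries. Mir409, Mir376a, Mir299a and Mir380 lie within it and have no row of their own. Reads at these genes, opposite to Gm24321, Gm25252, Mir299b and Gm25750, stood at 5104, 3123, 2061 and 790 CPM. They are not in this share. The highest members of the cluster with a row were Mir411, Mir127 and Mir487b, at 12259 ± 563, 8433 ± 717 and 7531 ± 725 CPM.

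Epithelial lists were compared next, regardless of their rank by share. The miR-200 family held 5.10% ± 0.0145 (SD, n = 2) of the reads, and each of its 5 members reached 10 CPM in both libraries. Its 3 highest members were Mir429, Mir200c at 14209 ± 993 CPM and Mir200b at 9392 ± 1997 CPM. Mir203 and Mir205, the list for stratified epithelium, held 3.34% ± 0.684, with 2.86% in replicate 1 and 3.82% in replicate 2. Mir205 alone stood at 11125 ± 331 CPM. The gastrointestinal epithelial list of miR-192, miR-194 and miR-215 was smaller at 0.397% ± 0.0281, led by Mir215 at 1755 ± 33.3 CPM, Mir192 at 1479 ± 244 CPM and Mir194-2 at 501 ± 41.5 CPM. The endocrine and pancreatic list held 1.17% ± 0.0982. Mir375 supplied most of it at 11125 ± 1179 CPM, against 453 ± 144 CPM for Mir7b and 130 ± 39.6 CPM for Mir7-1. Mir194-2 and Mir7-1 share a 20-base stretch with another hairpin.

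Lists for other cell types held between 0.00765% and 2.90% of the reads. The endothelial list, with Mir126a as its only measured member, held 2.90% ± 0.00147 (SD, n = 2). The mesenchymal list of miR-199 and miR-214 held 0.844% ± 0.124, led by Mir214 at 6647 ± 336 CPM and Mir199b at 1670 ± 891 CPM. Mir199b had 17788 reads in replicate 1 and 8306 in replicate 2, and it shares a 20-base stretch with another hairpin. The striated muscle list held 0.178% ± 0.223, an SD above its mean, with 0.336% in replicate 1 and 0.0205% in replicate 2. Mir122, the hepatocyte miRNA gene, held 0.152% ± 0.0432. The leukocyte list held 0.142% ± 0.00874, led among sense reads by Mir223 at 1203 ± 52.3 CPM, and rose to 0.265% when both strands were counted. Reads opposite to Mir142b, where Mir142 lies, stood at 1317 ± 366 CPM. The neuronal list held 0.136% ± 0.0206, almost all of it Mir137 at 1262 ± 193 CPM. Mir124a-1, Mir124a-2 and Mir124a-3 had no read, and these genes, Mir9-2 and Mir9-3 share a 20-base stretch with another hairpin, so the share of this list is uncertain. The same holds for the striated muscle genes Mir133a-1 and Mir133a-2, which had no read. The erythroid list held 0.0915% ± 0.0459, with 0.124% in replicate 1 and 0.0591% in replicate 2. The list for multiciliated cells held 0.0499% ± 0.00375, led by Mir34c at 257 ± 24.4 CPM, and the pluripotency clusters miR-290 and miR-302 held 0.00765% ± 0.000612.

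Among the remaining families and loci, the family of miR-23, miR-27 and miR-24 held 4.30% ± 1.00 (SD, n = 2), with 3.59% in replicate 1 and 5.01% in replicate 2. The miR-17-92 cluster and its paralogs, known from proliferating cells, held 3.85% ± 0.412, led by Mir17, Mir93 and Mir20a. The Hox-cluster miRNAs held 3.43% ± 0.238, miR-26 held 2.81% ± 0.361, miR-30 held 2.49% ± 0.450 and the list of miR-15, miR-16, miR-195, miR-322 and miR-497 held 2.26% ± 0.124. The miR-181 family held 0.757% ± 0.0645 and the imprinted H19-Igf2 locus 0.180% ± 0.0892, with 0.243% in replicate 1 and 0.117% in replicate 2. The lowest shares were those of miR-148 with miR-152 at 0.162% ± 0.0153, miR-221 with miR-222 at 0.0324% ± 0.00336 and miR-29 at 0.0156% ± 0.00148. Members sharing a 20-base stretch with another hairpin include Mir23a, Mir23b, Mir27b, Mir92-1, Mir26a-1, Mir26a-2, Mir16-1, Mir181a-1, Mir29b-1, Mir29b-2 and Mir29c. The shares of their lists are therefore uncertain, that of miR-29 among them. The miR-30 list holds the numbered copies Mir30c-1 and Mir30c-2, so its share is uncertain too. By the median level of its members, 15 of the 28 lists stood above 95% of 10000 random lists of the same size drawn from genes with a read. With genes at 10 CPM or more as the background that count was 6, and by the highest member of each list it was 7.

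**Figure D2:**
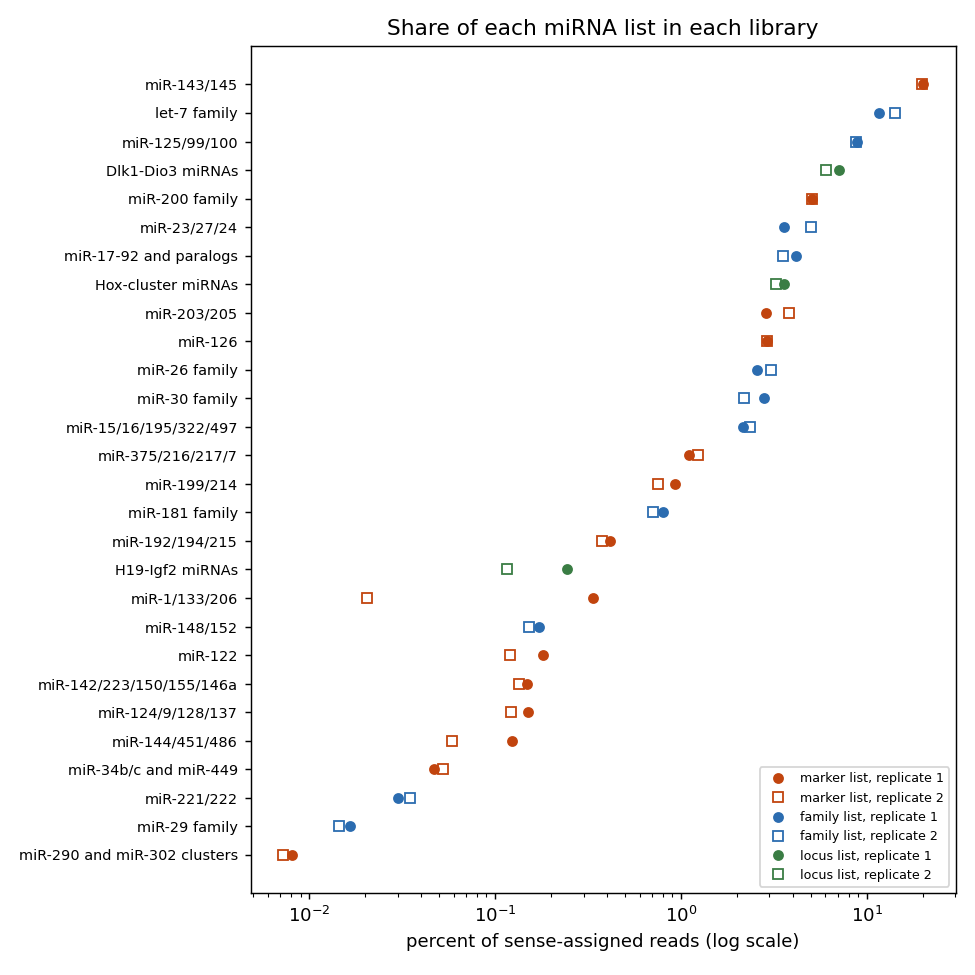
Share of sense-assigned reads held by each of the 28 fixed miRNA lists, in percent on a log axis, with filled circles for replicate 1 and open squares for replicate 2. The list of miR-143 and miR-145 is highest at a mean of 19.97%, and the striated muscle list of miR-1, miR-133 and miR-206 shows the widest gap between libraries, at 0.336% and 0.0205%.

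The last question was how closely the 2 libraries agreed and which genes set them apart. Mir206, a miRNA gene of skeletal muscle on chromosome 1 from 20679010 to 20679082, was 28.1-fold higher in replicate 1, with 24624 reads against 797 (log2 ratio 4.81, 95% interval 4.71 to 4.92). Mir133b, its neighbour from 20682769 to 20682887, was 8.59-fold higher in replicate 1, with 193 reads against 20. Mir499, in an intron of the muscle myosin gene Myh7b, was 4.97-fold higher, with 297 reads against 54. Of the 4 striated muscle genes tested, these 3 were higher in replicate 1, both when adjusted over the list alone and over all genes tested. The fourth, Mir208b in an intron of Myh7, had 851 reads against 712, a ratio of 1.09 that did not pass the test. Mir133b and Mir499 reached a mean of 10 CPM only through replicate 1, since they stood at 2.51 and 6.76 CPM in replicate 2. List members with reads but too low to test had 35 reads in replicate 1 and 25 in replicate 2 (Mir208a), 8 and 22 (Mir1b), and 4 and 3 (Mir1a-1). Mir193b was 6.85-fold higher in replicate 1 and Mir129-1 was 6.46-fold higher. Mir129-1 and Mir133b each share a 20-base stretch with another hairpin. The erythroid gene Mir451a was 2.29-fold higher in replicate 1, the only 1 of the 3 erythroid genes to differ when adjusted over the list alone and over all genes. Two-sided exact binomial tests of the read counts with Benjamini-Hochberg adjustment gave an adjusted p of 1.07e-32 for Mir133b, 1.86e-278 for Mir193b, 7.18e-77 for Mir129-1 and 2.28e-36 for Mir499.

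In the other direction, Mir196b, in an exon of Hoxa9, had 2166 reads in replicate 1 and 4161 in replicate 2, a ratio of 0.474. Mir15b, in an intron of Smc4, had 2925 and 5470 reads, a ratio of 0.486. The same exact test gave adjusted p values of 2.78e-184 for Mir196b and 8.39e-228 for Mir15b. Neither passed the 2-fold threshold when the libraries were scaled by total assigned reads. Of the 40 Dlk1-Dio3 genes tested, 6 were higher in replicate 1 and none lower, when adjusted over the list alone and over all genes; these were Mir329, Mir495, Mir496a, Mir667, Mir668 and Mir758. Mir30b was the only miR-30 gene of 6 to differ by the same test, and it was higher in replicate 1, but at a log2 ratio of 0.99 with DESeq2 size factors it missed the 2-fold threshold. No other member of the 28 lists was called with this scaling, while scaling by total assigned reads also called Mir125a, Mir145a, Mir199b, Mir34b, Mir483 and Mir493 as higher in replicate 1.

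In all, 23 of 289 genes at a mean of 10 CPM or more differed at least 2-fold between the libraries at an adjusted p under 0.05, 21 higher and 2 lower in replicate 1. Scaling by total assigned reads gave 29 higher and 0 lower, since it moved the median log2 ratio of all tested genes from 0.02 to 0.21. Within 1.5-fold lay 231 of the 289 genes. Across these genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.982 and Spearman's rho was 0.981. The biological coefficient of variation estimated by edgeR was 0.294. A chi-square statistic of 199754 on 750 degrees of freedom over all genes with a read showed that the 2 libraries differed by far more than counting error, so they were kept as separate samples. Genes at the depth of the highest levels differ beyond counting error at small folds, and 220 genes passed the test when no minimum fold was set.

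**Figure D3:**
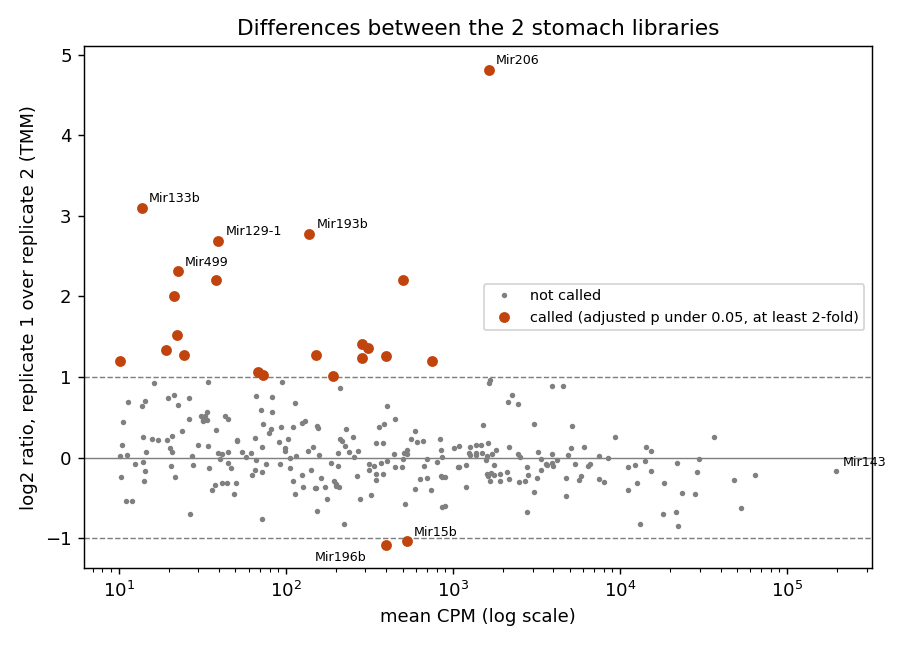
Ratio of replicate 1 over replicate 2 on the log2 scale after scaling by trimmed mean of M values, against mean CPM on a log axis, for the 289 miRNA genes at a mean of 10 CPM or more. Larger points mark the 23 genes called different at 2-fold or more, 21 above and 2 below, with Mir206 highest at 4.81.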

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

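The tests on Mir206, on the opposite strand and on multi-copy genes, and the bootstrap intervals over genomic clusters, were chosen after the results were seen. The test of hairpin GC content and the cluster ratio over all genes were set before. The design names a single group, so no biological explanation tied to a group was tested.

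Reads on the strand opposite to the annotated gene, which the main profile leaves out, formed a signal at 7 loci above 1000 CPM in both libraries, far over the floor of 3 counts. The mean levels (SD, n = 2) were 9868 ± 1663 CPM opposite to Gm25301, 5959 ± 869 CPM opposite to Gm25927, 5104 ± 195.5 CPM opposite to Gm24321, 3123 ± 373 CPM opposite to Gm25252, 2690 ± 184 CPM opposite to Gm24083, 2061 ± 282 CPM opposite to Mir299b and 1317 ± 366 CPM opposite to Mir142b. In the newer annotation the miRNA genes on that other strand are, in the same order, Mir378a, Mirlet7e, Mir409, Mir376a, Mir191, Mir299a and Mir142.

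Incomplete strand marking would place reads opposite to every abundant gene, yet the 100 genes with the most sense reads had 0.0028% of their reads on the other strand, under the 0.1% set as a bound. A candidate explanation is a miRNA gene on the opposite strand that has no row of its own in the count tables, and 99.96% of the opposite-strand reads lay at genes with such a partner. At the level measured, the locus opposite to Gm25301 would rank 24 among the genes of the profile.

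Across 289 genes, hairpin GC content and the log2 ratio between libraries had a Spearman rho of 0.0396, which argues against a trend with hairpin GC over all tested genes. Since 231 of these genes lay within 1.5-fold, the rho cannot decide on GC for the genes that differed. Of the 23 genes that differed between the libraries, Mir206 stood farthest apart, 28.1-fold higher in replicate 1. Its log2 ratio of 4.81 compares with an SD of 0.64 over the 289 genes, but it was picked as the farthest gene, so the share as far from a ratio of 1, 0.346%, is fixed by that choice; the median of the 3 other muscle genes lay above 99.93% of random lists matched on level, and above 95.03% without its neighbour Mir133b, short of the bound set for excluding it, so spread falling on genes one by one stays open. Striated muscle carried into the replicate 1 pool may be a source, since 2 of the 3 other muscle genes with at least 100 reads were at least 2-fold higher there, but Mir208b, at a log2 ratio of 0.12, was not, so the source stays open. If members of a genomic cluster differed together, ratios would be alike within clusters, and over 42 clusters the pooled SD of the log2 ratio within clusters was 0.634 of the SD over the same genes (bootstrap 95% interval 0.402 to 0.951; permutation p = 0.0001, the smallest that 10000 permutations give), between the bounds of 0.5 and 0.8. Without Mir206 and Mir133b it was 0.886 (0.731 to 0.973; permutation p = 0.0078), so the value rests largely on that pair; the interval lies above 0.5, but most genes in the comparison did not differ 2-fold, so how far the 23 genes differ by cluster cannot be told.

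Genes with several copies were weighed because reads placed in several positions form a separate total, from which it is inferred that no gene count holds them. Only genes with a Mir symbol were compared. Over all of these with a read, genes sharing a 20-base stretch with another hairpin had a median log2 level 2.46 above the others (119 and 580 genes, permutation p = 0.0025). Among those at 10 CPM or more the difference was -1.98 (68 and 220 genes, permutation p = 0.0014). Both comparisons keep genes by their counted reads and leave out 104 sharing Mir genes with no read, Mir124a-1 and Mir133a-1 among them. Neither therefore decides for or against a loss of reads. Whether such a loss lowers the counts of multi-copy genes cannot be told from these tables.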

How the results depend on the processing

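Opposite-strand reads added at genes without sense reads, and the 20-base definition of a copy, were alternatives chosen after seeing the data. The count of 277 expressed genes ran from 186 at 100 CPM to 409 at 1 CPM, and 281 to 289 with 1 library left. The share of the 10 most abundant genes was 44.3% without the most abundant gene, by construction, and 52.4% to 54.2% with 1 library left. With no filter on low counts Pearson's r was 0.991 and Spearman's rho 0.927 over 751 genes, against 0.982 and 0.981. With 1 choice changed at a time the coefficient of variation ran from 0.288 to 0.322. The count of differing genes was 23 with TMM, 21 with DESeq2 size factors and 29 with total reads. With no filter, where 751 genes were tested and the TMM factors were estimated anew, it was 50. With no minimum fold, which can only add calls, it was 220. Of the 29, 21 were shared with TMM. Lists above 95% of random lists numbered 15, but 7 by the highest member and 6 against genes at 10 CPM or more; the cause was not tested. They numbered 15 with either library left out. Numbered copies had a median log2 level 3.23 above other miRNA genes (permutation p = 0.0071), 2.66 to 3.48 with 1 library left, but -2.42 among genes at 10 CPM or more (permutation p = 0.0023); the cause was not tested. Counting both strands moved 5 of 28 list shares and 12 of 85 gene levels by more than 1 SD. The largest move was 1.87-fold for the leukocyte list, where Mir142 lies opposite to Mir142b. The lowest ratio to the main value was 0.967 for list shares and for gene levels, since opposite-strand reads also enlarge the total. Where the SD of 2 libraries was small, a fall of that size counted as moved. No paired analysis was possible because the series has a single group, so the replicate numbers pair nothing. Depth limits statements on genes under about 3 counts per library.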

Other observations

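The test of levels within clusters, its bound, bootstrap interval and repeat on genes sharing no stretch, and the choice of the low cluster members named here were made after the values were seen. Members of one genomic cluster stood at very different measured levels. On the X chromosome Mir322 reached 18242 ± 1170 CPM (SD, n = 2), while Mir450-2, in the same cluster of 7 expressed members, stood at 11.9 ± 2.07 CPM, a 1528-fold range. Mir17, of the cluster known from proliferating cells, stood at 15359 ± 1970 CPM and Mir19a of the same transcript at 40.6 ± 3.16 CPM, a 379-fold range. Mir99a was 421-fold above its neighbour Mirlet7c-1, and Mir143 was 49.8-fold above Mir145a, with 37.0-fold in replicate 1 and 76.7-fold in replicate 2. Mirlet7c-1 and Mir450-2 share a 20-base stretch with another hairpin, so their levels are uncertain, while Mir19a and Mir145a share none.

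A pooled SD of log2 CPM within clusters of at most 0.5 times the SD over the same genes was the bound chosen for 1 hypothesis. That hypothesis held that one primary transcript alone sets the measured level of all members. Over 42 clusters and 141 genes the ratio was 0.908 (bootstrap 95% interval 0.799 to 1.01, permutation p = 0.014). Among the 91 genes that share no 20-base stretch, in 23 clusters, it was 0.832 (0.677 to 0.945). Neither interval lies wholly above 0.8, the bound first set against the hypothesis. The comparison with 0.5, the bound set for it, was made after the values were seen. Both intervals lie above 0.5, and Mir17 exceeded Mir19a 391-fold in replicate 1 and 364-fold in replicate 2. These values argue against the hypothesis for the measured levels of all members, although the permutation test shows levels somewhat closer within clusters than chance gives. A bias between miRNA sequences that both libraries share could also spread measured levels. The values therefore do not tell whether cluster members differed in abundance in the tissue.

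By place in the genome, miRNA genes in introns of same-strand genes held 35.7% ± 0.711 (SD, n = 2) of the sense-assigned reads, those in exons 23.3% ± 0.417 and those outside same-strand genes 41.0% ± 0.294. Mir143 alone, which lies outside same-strand genes, held 19.6%, so the order of these places rests on that gene. Chromosome 12, which carries the Dlk1-Dio3 cluster, held 9.09% ± 0.0614, with 48 genes at 10 CPM or more in both libraries. Opposite-strand reads, among them those at Mir409, Mir376a, Mir299a and Mir380, are not in this share. The X chromosome held 5.19% ± 0.0918, with 33 such genes.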
